A study of Rattus norvegicus with 78 samples.

How the data were processed

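Male rat offspring of a line bred for low locomotor response to novelty were profiled on single-colour NimbleGen expression arrays, in hippocampus and amygdala at postnatal days 7, 14, 21 and 75. Per the labels' protocols, dams received paroxetine at 10 mg per kg per day in drinking water or plain water, RNA was isolated with TRIzol, linearly amplified, converted to double-stranded cDNA and labelled with Cy3. The 78 arrays were grouped from their labels into 16 groups of region, age and treatment, with 5 arrays each and 4 in both exposed P7 groups.

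The authors deposited 1 table of normalized intensity values on a linear scale for all arrays. The normalization and its settings are not given in the sources used here, although column names of other deposited tables mention RMA. The regions appear to have been normalized separately, because array pairs of the same region share a median of 329 identical values and pairs of different regions 85, so that levels set across regions carry that limit. The authors also deposited 8 comparison tables, which per the file headers hold the p-value of an unpaired t-test, the same after Bonferroni correction, and the absolute fold change, kept at a corrected p of at most 0.05 and a fold of at least 1.5. Per the file headers the features had first been filtered on the sample data. The 312 per-array columns of those tables (39 in each of 8) have names that match no label and were not used.

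The value table held 26420 rows, of which 1 was a random control probe, leaving 26419 features, 10113 with NM and 16306 with XM accessions. Symbols came from a RefSeq gene table of assembly GRCr8, used for names only, for 9747 features, and from the comparison tables for 41, while 16631 stayed unnamed here. A gene was represented by its feature with the highest mean log2 value, which gave 9667 genes. Intensities were taken to log2 with no pseudocount and no further normalization. Linear models were fitted with limma 3.58.1 (R 4.3.3, statmod 1.5.0) to all arrays of a region, with group as the only term, followed by eBayes, two-sided tests and Benjamini-Hochberg adjustment over all features at 0.05. Contrasts were exposed minus control at each age, their average, an F test of equal differences over the ages, and P75 minus P7 in controls. Fits of all 78 arrays gave the region by treatment terms and the regions' difference in controls. Fits within the exposed arm were added later.

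The 33 gene lists covered neuronal pathways, metabolism, cell types of brain, blood and choroid plexus, neighbouring regions and receptors of the nose. They, the rule for named genes, the tests and most alternatives were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists of a comparison, and again with an estimated correlation. Over the 8 comparisons of exposed and control rats camera called 82 list shifts, and 34 with an estimated correlation. An exact two-sided permutation test of the mean list score was run beside it, with a smallest possible p of 0.00794. Named genes, apart from 5 serotonin genes named whatever their level, had a mean above the median of their region. They were the 8 largest rises and falls per age and region, the 4 members with the smallest p of each called list, and the leading genes of the other contrasts. The text names a selection of these, and some of them are not reported here.

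The steps ran on simulated data with few changes, so real error rates may differ, especially for lists, whose calls depended on the correlation used. With 100 features changed by 1 log2 unit in the hippocampus at P7, 53 were recovered, and of 100 changed by 0.5, 11 were, with 1 false call among 26419. For a change in 1 group, the region by treatment term at P7 recovered 28 and 3 of 100, the hippocampal age by treatment term 25 and 2, and the hippocampal average 6 and 0. A list lowered by 0.5 among 9667 amygdalar genes at P14 was recovered, and runs with no change gave 0 false calls.

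Alternatives were quantile normalization over 78 arrays, leaving out the dimmer 50% of features, trend and robust moderation, array weights, leaving out each array, a replicate block, fits of only the groups compared or of all arrays, and plain t-tests. Fits on subsets of arrays and with the random control probe as a covariate were chosen after seeing the data. For each result 100 splits of the arrays were drawn. Quantile normalization moved the median difference of all features by at most 0.0595 in size in any comparison. The array number limits the precision of every value.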

Results

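Transcript levels were measured in the hippocampus and the amygdala of male rats from a line bred over generations for low locomotor response to a new environment (Low Responders). Their dams drank paroxetine, a selective serotonin reuptake inhibitor, at 10 mg per kg per day, or plain water, from the week before conception until the pups were weaned at P21. Offspring of both arms were sampled at P7, P14, P21 and P75, so the question at each age was whether exposure before and after birth changed gene expression in either region. The 78 single-colour arrays formed 16 groups of region, age and treatment. Each group held 5 arrays, except the exposed P7 group of each region, which held 4. Of 26419 features tested, 9667 stood for a named gene. Arrays of the same group correlated at 0.926 to 0.985 (median 0.968). The labels do not say which pups shared a litter, so p-values measure only the spread between these arrays, and the number of arrays limits the precision. Values below are log2 differences, exposed minus control, ± the standard error of the limma fit, with n = 5 per group and n = 4 in the exposed P7 groups. A gene is said to rise or fall only where its Benjamini-Hochberg adjusted p was under 0.05.

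Array measures that belong to no gene also separated exposed from control arrays. A random-sequence control probe, which matches no transcript, read 52.97 ± 1.61 (SD, n = 4) on exposed hippocampal arrays at P7 against 43.97 ± 0.381 (n = 5) on controls, a difference with an exact two-sided p of 0.00794, the smallest these group sizes allow (adjusted over the 8 comparisons, 0.00907). In the hippocampus it was also higher on exposed arrays at P14 (48.57 against 45.2) and lower at P21 (47.64 against 55.19) and P75 (49.0 against 56.29). In the amygdala it was lower at P7 (44.63 against 48.9) and P75 (46.09 against 50.77), higher at P21 (46.71 against 45.31), and not separable at P14 (46.14 against 47.15, exact p = 0.159). The interquartile range of log2 intensity moved as well, for example from 3.21 on control to 2.79 on exposed hippocampal arrays at P7. Genes for olfactory and vomeronasal receptors, which brain tissue hardly expresses, were called in 37.3% of cases there, with a median of 0.43. No batch is given for any array, so treatment was not separable by label from an array batch in the comparisons that follow.

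**Figure D1:**
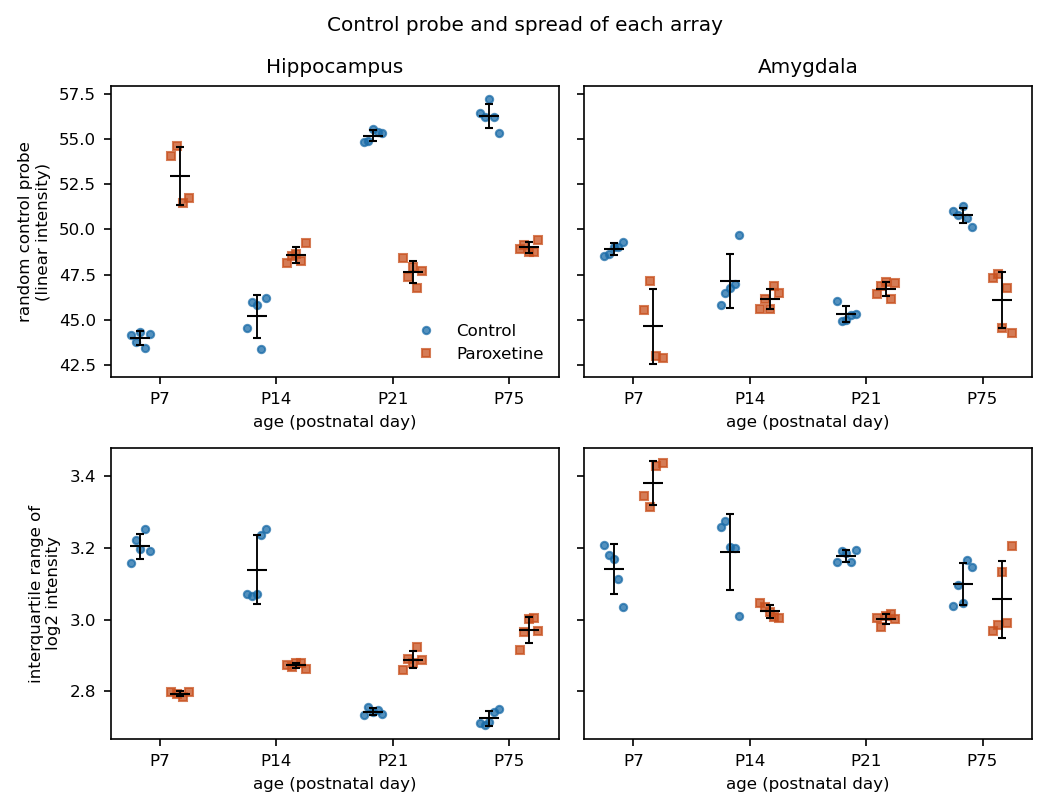
Intensity of the random control probe (top, linear scale) and interquartile range of log2 intensity (bottom) on each of 78 arrays, by age in postnatal days, for hippocampus (left) and amygdala (right). Points are arrays, circles controls and squares paroxetine, and black bars give mean ± SD; the probe reads higher on exposed hippocampal arrays at P7 and P14 and lower at P21 and P75.

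At P7 the hippocampus of exposed pups held less transcript of neuronal, astrocytic and cholesterol synthesis genes and more transthyretin. The strongest falls among named genes were those of Ptprs (-3.74 ± 0.13), Tbc1d14 (-3.69 ± 0.20), and Vmp1 (-3.50 ± 0.17). Rises were led by 4930488N24Rikl (3.54 ± 0.22), Cpg1 (3.43 ± 0.18), Asgr2 (2.86 ± 0.22) and Ttr, secreted by choroid plexus (2.35 ± 0.16).

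Of 22 measured genes of cholesterol synthesis, 21 fell and 1 was not called (21 passed adjusted over the list alone), with Hmgcs1 at -2.30 ± 0.13, Msmo1 at -2.56 ± 0.18 and Cyp51 at -1.90 ± 0.16. Cholesterol synthesis had a camera adjusted p of 1.72e-07, and adjusted p = 0.0081 with an estimated correlation. Glutamate receptor genes followed, since of 19 measured, 13 fell and 6 were not called (13 passed adjusted over the list alone), including Grm5 (-2.42 ± 0.18), Grik2 (-1.88 ± 0.14) and Grin1 (-1.41 ± 0.11). By camera, glutamate receptors had adjusted p = 0.000469, and adjusted p = 0.0159 with an estimated correlation. Presynaptic release genes such as Syp (-2.18 ± 0.10) and Sv2a (-1.99 ± 0.10) were lower too, since of 27 measured, 18 fell, 4 rose and 5 were not called (22 passed adjusted over the list alone). For release machinery camera gave adjusted p = 0.000414, and adjusted p = 0.137 with an estimated correlation. Markers of immature neurons (of 15, 13 fell and 2 were not called, 14 passed adjusted over the list alone) included Tubb2b (-2.27 ± 0.098) and Gap43 (-1.27 ± 0.12) and shifted down. Immature neuron markers had a camera adjusted p of 6.19e-05, and adjusted p = 0.0159 with an estimated correlation. Astrocyte markers (of 20, 14 fell, 1 rose and 5 were not called, 16 passed adjusted over the list alone) shifted down as well, among them the glutamate transporter Slc1a3 (-2.35 ± 0.12) and the gap junction gene Gja1 (-2.05 ± 0.10). By camera, astrocyte markers had adjusted p = 0.000104, and adjusted p = 0.0081 with an estimated correlation. Ribosomal protein genes (of 65, 49 fell, 4 rose and 12 were not called, 59 passed adjusted over the list alone) and oxidative phosphorylation genes (of 41, 27 fell, 3 rose and 11 were not called, 30 passed adjusted over the list alone) were lower as groups, with Rpl8 (-2.73 ± 0.16) and Atp5f1a (-2.26 ± 0.10) as examples. For ribosomal proteins and oxidative phosphorylation genes, camera gave adjusted p = 1.76e-07 and adjusted p = 6.19e-05. These had adjusted p = 0.0122 and adjusted p = 0.0176 with an estimated correlation. Choroid plexus markers rose, since besides Ttr the list held Sostdc1 (1.53 ± 0.18) and Folr1 (0.79 ± 0.18) and of 15 measured, 9 rose and 6 were not called (9 passed adjusted over the list alone). By camera, choroid plexus markers had adjusted p = 0.00185, and adjusted p = 0.0159 with an estimated correlation. Receptors not expected in brain moved the other way from the neuronal groups (of 1232, 456 rose, 4 fell and 772 were not called, 410 passed adjusted over the list alone). For olfactory and vomeronasal receptors camera gave adjusted p = 1.66e-16, and adjusted p = 4.08e-11 with an estimated correlation.

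By limma, 6626 rose and 7470 fell among 26419 features (14096 called), and 1916 of 9667 genes rose while 3267 fell; camera called 12 of 33 lists. With the random control probe, which follows the groups, as a covariate 1712 were called. Bright genes in general moved down, with a median of -0.25 for the brightest 10% of all features and 0.23 for the dimmest. Quantile normalization across arrays ended the calls of GABA-A receptor subunits (adjusted p = 0.0287, then 0.051), postsynaptic scaffold genes (0.0213, then 0.391) and chromatin enzymes (0.037, then 0.103), with falls among their members, for example Gabra3 (-1.86 ± 0.19) and Dlg2 (-2.35 ± 0.11). With an estimated correlation these lists had adjusted p = 0.223, adjusted p = 0.273 and adjusted p = 0.137, and the chromatin call also ended without control replicate 4 (0.0523) or exposed replicate 4 (0.0546).

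A week later many of the same genes were still lower in the exposed hippocampus. At P14 the falls were led by Vmp1 (-2.75 ± 0.16), Ptprs (-2.71 ± 0.12) and Tbc1d14 (-2.69 ± 0.19). Cpg1 (2.24 ± 0.17), C1h16orf54 (2.18 ± 0.27) and Asgr2 (1.39 ± 0.20) rose. Of the genes called, 2287 fell and 711 rose at both P7 and P14, where independent lists of these sizes would share 868.5 and 225.2, and 12 rose then fell while 30 fell then rose. Across all 9667 genes the P7 and P14 differences, which share no arrays, correlated at r = 0.814, although genes are not independent replicates. The control arrays at P14 fell into 2 sets on the first principal component of the hippocampal arrays, replicates 1 to 3 at -51.4 to -47.5 and replicates 4 and 5 at -82.2 and -92.6, and limma called 6147 features against the former alone and 11081 against the latter. Exposed arrays at P7 were split on the second component, replicates 1 and 2 at -11.2 and -11.6 and replicates 3 and 4 at -58.1 and -57.3, with 12498 and 12288 features called for each pair alone. The reason for either split is not known, and these fits were chosen after the data were seen.

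Synaptic groups were again lower. Of 19 glutamate receptor genes 14 fell, 1 rose and 4 were not called (15 passed adjusted over the list alone), among them Grin2b (-1.45 ± 0.13) and Gria3 (-1.30 ± 0.12). Glutamate receptors had a camera adjusted p of 5.58e-05, and adjusted p = 0.0129 with an estimated correlation. Release machinery (of 27, 18 fell, 1 rose and 8 were not called, 21 passed adjusted over the list alone) included Syn2 (-1.19 ± 0.13), and postsynaptic scaffold genes (of 24, 15 fell, 2 rose and 7 were not called, 18 passed adjusted over the list alone) included Dlg2 (-1.79 ± 0.10) and Homer1 (-1.21 ± 0.13). In turn for release machinery and postsynaptic genes, camera gave adjusted p = 9.42e-06 and adjusted p = 0.000487. Estimating the correlation gave adjusted p = 0.057 and adjusted p = 0.121. The chloride exporter gene Slc12a5 (-1.22 ± 0.15) stood in a list of GABA-A receptor subunits and chloride transporters in which, of 16, 9 fell and 7 were not called (9 passed adjusted over the list alone). GABA-A receptor subunits had a camera adjusted p of 0.014, and adjusted p = 0.207 with an estimated correlation. Cholesterol synthesis (of 22, 17 fell and 5 were not called, 19 passed adjusted over the list alone) stayed lower, with Hmgcs1 at -1.73 ± 0.12. By camera, cholesterol synthesis had adjusted p = 4.19e-05, and adjusted p = 0.0411 with an estimated correlation. Chromatin and DNA methylation enzymes (of 11, 9 fell and 2 were not called, 9 passed adjusted over the list alone) included Dnmt3a (-1.04 ± 0.16). For chromatin enzymes camera gave adjusted p = 0.00482, and adjusted p = 0.0565 with an estimated correlation. Vascular markers fell as a group (of 20, 12 fell and 8 were not called, 12 passed adjusted over the list alone), with the tight junction gene Cldn5 at -1.75 ± 0.14, as did astrocyte markers (of 20, 12 fell, 1 rose and 7 were not called, 13 passed adjusted over the list alone), with Slc1a3 at -1.53 ± 0.12. For vascular markers and astrocyte markers, camera gave adjusted p = 0.000902 and adjusted p = 0.00194. At an estimated correlation they had adjusted p = 0.0417 and adjusted p = 0.0368. Olfactory and vomeronasal receptors were shifted up (of 1232, 225 rose, 10 fell and 997 were not called, 167 passed adjusted over the list alone). For olfactory and vomeronasal receptors camera gave adjusted p = 1.46e-10, and adjusted p = 8.91e-09 with an estimated correlation. In total 4236 rose and 5865 fell among the features by limma, with camera calling 10 of 33 lists, and 4624 were called with the random probe as covariate. The tenth, choroid plexus (of 15, 4 rose and 11 were not called, 4 passed adjusted over the list alone), lost its call after quantile normalization (0.0578) and without control replicate 2 (0.0582), control replicate 5 (0.055) or exposed replicate 2 (0.0718). Choroid plexus markers had a camera adjusted p of 0.0368, and adjusted p = 0.109 with an estimated correlation.

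At weaning the hippocampal differences pointed the other way for energy and protein synthesis genes. Ttr, higher at P7, fell by 1.98 ± 0.15 at P21, and the MHC gene RT1-O1 (-1.95 ± 0.23) and Ccdc134 (-1.80 ± 0.21) fell with it. The rises were led by H2ac1, a histone H2A gene (2.11 ± 0.34), C6h14orf180 (1.95 ± 0.31), and the complement genes C4b (1.83 ± 0.26) and C4a (1.60 ± 0.32), near-identical copies that probes may not tell apart.

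Ribosomal protein genes (of 65, 42 rose and 23 were not called, 50 passed adjusted over the list alone) were higher, for example Rpl13a (0.89 ± 0.11) and Rps6 (0.72 ± 0.097), and so were genes of oxidative phosphorylation (of 41, 24 rose and 17 were not called, 28 passed adjusted over the list alone), for example Atp5g3 (0.97 ± 0.14) and Ndufs5 (0.64 ± 0.11). In turn for ribosomal proteins and oxidative phosphorylation genes, camera gave adjusted p = 8.6e-15 and adjusted p = 9.2e-09. The estimated correlation gave adjusted p = 0.000298 and adjusted p = 0.00165. Postsynaptic genes (of 24, 11 rose and 13 were not called, 15 passed adjusted over the list alone) such as Camk2n1 (0.61 ± 0.10) were shifted up. Postsynaptic genes had a camera adjusted p of 1.81e-05, and adjusted p = 0.0574 with an estimated correlation. Astrocyte markers (of 20, 12 rose, 1 fell and 7 were not called, 14 passed adjusted over the list alone), with the water channel Aqp4 at 0.80 ± 0.12, were higher, a call that quantile normalization ended (0.0595). By camera, astrocyte markers had adjusted p = 0.000422, and adjusted p = 0.0101 with an estimated correlation. Quantile normalization also ended, at the adjusted p given last in each bracket, the calls of immature neurons (of 15, 9 rose and 6 were not called, 10 passed adjusted over the list alone, Tubb2b 0.53 ± 0.092; 0.0525), release machinery (of 27, 10 rose and 17 were not called, 10 passed adjusted over the list alone, Syn1 0.68 ± 0.100; 0.292) and chaperones (of 21, 11 rose, 1 fell and 9 were not called, 15 passed adjusted over the list alone, Hsp90b1 0.64 ± 0.11; 0.0665). For immature neuron markers, release machinery and chaperones, camera gave adjusted p = 0.000421, adjusted p = 0.000545 and adjusted p = 0.00475. They had adjusted p = 0.0407, adjusted p = 0.178 and adjusted p = 0.0621 with an estimated correlation. Choroid plexus markers went down with Ttr (of 15, 4 fell and 11 were not called, 4 passed adjusted over the list alone), as did olfactory and vomeronasal receptors (of 1232, 176 fell, 47 rose and 1009 were not called, 195 passed adjusted over the list alone). In turn for choroid plexus markers and olfactory and vomeronasal receptors, camera gave adjusted p = 0.00371 and adjusted p = 2.31e-05. These had adjusted p = 0.0306 and adjusted p = 2.47e-05 with an estimated correlation. By limma 4171 rose and 2806 fell among the features, and camera called 11 of 33 lists, but with the random probe as covariate 2 features were called. The brightest 10% of all features had a median of 0.28 and the dimmest 10% one of -0.15, so bright genes in general moved up. Calls for interneurons (adjusted p = 0.0283, adjusted p = 0.225 with an estimated correlation) and for dopamine and noradrenaline genes (adjusted p = 0.0294, adjusted p = 0.18 with an estimated correlation) ended after quantile normalization (0.129 and 0.0644). The interneuron call also ended without control replicate 3 (0.0527), and the dopamine call without control replicate 1 (0.0627) or 2 (0.0813).

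In exposed adults, long after paroxetine ended at weaning, hippocampal genes of synapses, mitochondria and ribosomes were higher than in controls. Atp2b4 (2.71 ± 0.15), Nr2f2 (2.17 ± 0.17), Atp6v1h (2.15 ± 0.19) and Rgs4 (1.85 ± 0.18) led the rises at P75. Ptprs, lower at P7 and P14, rose (1.84 ± 0.12). Cpg1, higher then, fell by 3.12 ± 0.17, and Fgf10 (-2.12 ± 0.27), Asgr2 (-1.94 ± 0.20) and the urocortin gene Ucn (-1.87 ± 0.18) fell with it. Of called genes, 2106 fell at P7 and rose at P75 and 825 rose then fell, against 939.5 and 288.2 for independent lists. The differences, which share no arrays, correlated at r = -0.671 across genes. The random probe changed sign too (8.99 units at P7, -7.29 at P75), so a batch stays open.

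Of 41 oxidative phosphorylation genes 38 rose and 3 were not called (40 passed adjusted over the list alone), for example Atp5me (1.59 ± 0.10) and Cox6c (1.12 ± 0.095), and of 65 ribosomal protein genes 59 rose and 6 were not called (60 passed adjusted over the list alone), for example Rpl23 (1.51 ± 0.13). For oxidative phosphorylation genes and ribosomal proteins, camera gave adjusted p = 1.47e-19 and adjusted p = 1.8e-20. Estimating the correlation gave adjusted p = 4.7e-06 and adjusted p = 1.51e-05. Release machinery (of 27, 23 rose and 4 were not called, 24 passed adjusted over the list alone) rose with Syngr1 (1.27 ± 0.10) and Sv2b (1.56 ± 0.13), and postsynaptic genes (of 24, 18 rose and 6 were not called, 18 passed adjusted over the list alone) with Dlg2 (0.95 ± 0.10) and Homer1 (0.94 ± 0.13). In turn for release machinery and postsynaptic genes, camera gave adjusted p = 1.06e-08 and adjusted p = 7.8e-05. At an estimated correlation they had adjusted p = 0.019 and adjusted p = 0.0908. Markers of immature neurons (of 15, 11 rose, 1 fell and 3 were not called, 12 passed adjusted over the list alone) were higher, among them Gap43 (1.51 ± 0.12) and Nnat (1.48 ± 0.13). Dcx, another such marker, stood at 7.65 ± 0.39 in exposed rats against 7.37 ± 0.48 in controls (log2, SD). For immature neuron markers camera gave adjusted p = 1.45e-05, and adjusted p = 0.0157 with an estimated correlation. Cholesterol synthesis, lower at P7 and P14, was higher (of 22, 17 rose and 5 were not called, 20 passed adjusted over the list alone), with Hmgcs1 (1.15 ± 0.12). Cholesterol synthesis had a camera adjusted p of 0.000435, and adjusted p = 0.081 with an estimated correlation. In the list of stress hormones and glucocorticoid targets, of 22 measured, 8 fell, 2 rose and 12 were not called (10 passed adjusted over the list alone), the falls including Ucn, the corticotropin-releasing hormone gene Crh (-1.42 ± 0.27) and the vasopressin gene Avp (-0.98 ± 0.23). By camera, stress hormone genes had adjusted p = 0.0154, and adjusted p = 0.0913 with an estimated correlation. Olfactory and vomeronasal receptors were lower (of 1232, 286 fell, 37 rose and 909 were not called, 265 passed adjusted over the list alone). For olfactory and vomeronasal receptors camera gave adjusted p = 3.89e-10, and adjusted p = 2.43e-08 with an estimated correlation.

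Limma called 11198 features at P75, of which 6274 rose and 4924 fell, and camera called 15 of 33 lists, but with the random probe as covariate 114 features were called. Bright genes in general moved up here as well, with a median of 0.42 for the brightest 10% of all features and -0.06 for the dimmest. After quantile normalization 7 upward list calls ended, with camera adjusted p-values as follows: GABA-A receptor subunits (0.0308, then 0.0992; adjusted p = 0.192 with an estimated correlation), glutamate receptors (0.0224, then 0.164; adjusted p = 0.105 with an estimated correlation), chaperones (0.0143, then 0.0826; adjusted p = 0.0913 with an estimated correlation), interneurons (0.0154, then 0.0992; adjusted p = 0.154 with an estimated correlation), myelin genes (0.0224, then 0.257; adjusted p = 0.177 with an estimated correlation), astrocytes (0.0154, then 0.349; adjusted p = 0.081 with an estimated correlation) and vascular markers (0.0386, then 0.0876; adjusted p = 0.154 with an estimated correlation). Members that rose in these lists included Gabra3 (1.48 ± 0.18), Grin1 (1.06 ± 0.10) and Hsp90b1 (1.19 ± 0.11). The vascular call also ended without control replicate 3 (0.0554) or exposed replicate 4 (0.0621).

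The amygdala of exposed pups had fewer called features at P7 than the hippocampus. Ttr (1.47 ± 0.34), Car12 (1.12 ± 0.26), Hspa14 (1.18 ± 0.25) and Psma5 (1.05 ± 0.20) rose. Gsn (-1.11 ± 0.21) and Ptgds (-1.07 ± 0.26) fell. Of 22 measured myelin genes, 4 fell and 18 were not called (4 passed adjusted over the list alone), the falls including the tight junction gene Cldn11 (-1.06 ± 0.27), which was not called without exposed replicate 3 (adjusted p = 0.0794). Myelin genes had a camera adjusted p of 0.000494, and adjusted p = 0.449 with an estimated correlation. Levels of myelin genes were not even among controls, since Mbp, the myelin basic protein gene, ranged from 10.13 to 12.26 (SD 1.07, n = 5) over the control arrays. An exact permutation of the list score did not separate the arms (adjusted p = 0.38).

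Oxidative phosphorylation genes were shifted up (of 41, 11 rose and 30 were not called, 18 passed adjusted over the list alone), with Atp5mg (0.97 ± 0.16) and Atp5g3 (0.72 ± 0.14), but not with the correlation estimated. By camera, oxidative phosphorylation genes had adjusted p = 9.19e-08, and adjusted p = 0.237 with an estimated correlation. Cholesterol synthesis was shifted up only at the preset correlation (of 22, 5 rose and 17 were not called, 7 passed adjusted over the list alone, Nsdhl 0.52 ± 0.10, Msmo1 0.66 ± 0.13). For cholesterol synthesis camera gave adjusted p = 0.000149, and adjusted p = 0.0931 with an estimated correlation. So were glutamate receptors (of 19, 2 rose and 17 were not called, 8 passed adjusted over the list alone, Grm5 0.56 ± 0.13) and ribosomal proteins (of 65, 7 rose and 58 were not called, 17 passed adjusted over the list alone, Rpl27 0.70 ± 0.15). For glutamate receptors and ribosomal proteins, camera gave adjusted p = 0.000731 and adjusted p = 0.00015. The estimated correlation gave adjusted p = 0.179 and adjusted p = 0.734. Olfactory and vomeronasal receptors were lower (of 1232, 55 fell, 3 rose and 1174 were not called, 36 passed adjusted over the list alone). For olfactory and vomeronasal receptors camera gave adjusted p = 1.75e-15, and adjusted p = 2.11e-06 with an estimated correlation. By limma 1496 rose and 573 fell among the features (72.3% higher), whereas after quantile normalization 521 rose and 566 fell (47.9% higher), with the random probe as covariate 106 rose and 163 fell, and the call count dropped to 961 without exposed replicate 3 and to 995 without exposed replicate 4. With these arrays fitted alone, without the other ages, 5 features passed. Camera called 9 of 33 lists, of which GABA-A receptor subunits (adjusted p = 0.0392, adjusted p = 0.449 with an estimated correlation), chaperones (adjusted p = 0.0392, adjusted p = 0.301 with an estimated correlation) and striatal markers (adjusted p = 0.0106, adjusted p = 0.301 with an estimated correlation) lost their call without control replicate 2 (0.0532, 0.0503 and 0.0503). The GABA-A call also ended after quantile normalization (0.0798) and without control replicate 4 (0.0854) or exposed replicate 1 (0.0761) or 2 (0.0504), and the chaperone call without control replicate 3 (0.0507) or 4 (0.0638) or exposed replicate 1 (0.0518), 3 (0.0878) or 4 (0.0682).

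At P14 single genes differed strongly in the exposed amygdala, whereas none of 8 list calls passed with an estimated correlation. Mospd3 (-1.69 ± 0.11), Igf2 (-1.64 ± 0.15), Rhoj (-1.64 ± 0.17) and Alox15 (-2.05 ± 0.25) fell. Ttr differed by -1.86 ± 0.33, but exposed arrays spread from 8.75 to 11.57 (SD 1.39, n = 5). Slc22a18 (2.72 ± 0.28), Mall (2.48 ± 0.27), the sperm protamine gene Prm1 (2.46 ± 0.32), the hair keratin gene Krt35 (2.21 ± 0.27) and the MHC class I gene RT1-CE11 (2.15 ± 0.31) led the rises.

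Interneuron genes shifted down (of 20, 7 fell, 2 rose and 11 were not called, 10 passed adjusted over the list alone), including the peptide genes Cck (-0.96 ± 0.090) and Sst (-0.73 ± 0.098) and the transcription factor gene Dlx5 (-0.95 ± 0.14). Interneuron genes had a camera adjusted p of 0.0374, and adjusted p = 0.306 with an estimated correlation. Vascular markers (of 20, 8 fell and 12 were not called, 8 passed adjusted over the list alone), among them Tagln (-1.03 ± 0.16) and Acta2 (-0.80 ± 0.14), were lower as well. By camera, vascular markers had adjusted p = 0.0233, and adjusted p = 0.306 with an estimated correlation. Thalamic markers (of 14, 6 fell, 1 rose and 7 were not called, 8 passed adjusted over the list alone) were lower, with Six3 (-1.11 ± 0.12) and Lef1 (-1.21 ± 0.16), as were postsynaptic genes (of 24, 10 fell, 2 rose and 12 were not called, 13 passed adjusted over the list alone), with the neuroligins Nlgn3 (-0.77 ± 0.11) and Nlgn1 (-0.74 ± 0.12), and markers of immature neurons (of 15, 6 fell and 9 were not called, 6 passed adjusted over the list alone), with Dpysl3 at -0.97 ± 0.13. In turn for thalamic markers, postsynaptic genes and immature neuron markers, camera gave adjusted p = 0.032, adjusted p = 0.032 and adjusted p = 0.0359. They had adjusted p = 0.103, adjusted p = 0.536 and adjusted p = 0.408 with an estimated correlation. Oxidative phosphorylation (of 41, 16 rose, 3 fell and 22 were not called, 19 passed adjusted over the list alone) was shifted up, with Atp5mc1 (1.34 ± 0.16) and Atp5me (0.74 ± 0.11), and so were ribosomal proteins (of 65, 19 rose, 10 fell and 36 were not called, 31 passed adjusted over the list alone, Rps7 2.07 ± 0.23). For oxidative phosphorylation genes and ribosomal proteins, camera gave adjusted p = 0.00788 and adjusted p = 0.032. These had adjusted p = 0.536 and adjusted p = 0.764 with an estimated correlation. Olfactory and vomeronasal receptors rose slightly as a group (of 1232, 252 rose, 93 fell and 887 were not called, 323 passed adjusted over the list alone). By camera, olfactory and vomeronasal receptors had adjusted p = 0.00247, and adjusted p = 0.0745 with an estimated correlation. Limma called 9460 features, of which 4361 rose and 5099 fell.

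Quantile normalization ended the P14 amygdala calls of interneurons, postsynaptic genes and immature neurons (0.147 for each). Leaving out 1 array ended the calls of ribosomal proteins (0.0992 without control replicate 5, 0.311 and 0.374 without exposed replicates 1 and 2), interneurons (0.061, 0.0512 and 0.0841 without control replicates 3 and 5 and exposed replicate 1), postsynaptic genes (0.0535 and 0.0647 without control replicate 4 and exposed replicate 2), immature neurons (0.0691, 0.061 and 0.0631 without control replicates 1 and 3 and exposed replicate 2) and thalamus (0.0504 without control replicate 5). In exact permutations of the list score, ribosomal proteins (0.409) and oxidative phosphorylation (0.0838) did not separate the arms.

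At P21 transthyretin was 17.0 times higher in the exposed amygdala (Ttr 4.08 ± 0.33), at 12.17 ± 0.13 against 8.09 ± 0.27 log2 (SD, n = 5 each). Amygdalar controls stood at 10.05, 11.91 and 11.91 at P7, P14 and P75, above their P21 level. Slc22a18 (2.01 ± 0.28), Fdcsp (2.49 ± 0.39) and Csf3 (1.71 ± 0.29) rose as well. Fads2 (-1.27 ± 0.11), the GABA-A subunit gene Gabrg3 (-1.27 ± 0.14), Pcbd1 (-1.40 ± 0.16) and Mospd3 (-1.23 ± 0.11) fell. Choroid plexus markers shifted up (of 15, 4 rose, 1 fell and 10 were not called, 5 passed adjusted over the list alone), with Clic6 at 0.66 ± 0.19, and the median of the list was 0.26. For choroid plexus markers camera gave adjusted p = 0.0167, and adjusted p = 0.0377 with an estimated correlation.

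Interneuron genes were lower (of 20, 12 fell, 1 rose and 7 were not called, 15 passed adjusted over the list alone), with Cck at -0.98 ± 0.090, Npy at -0.63 ± 0.11 and Reln at -0.68 ± 0.15. Interneuron genes had a camera adjusted p of 0.00493, and adjusted p = 0.0377 with an estimated correlation. Thalamic markers (of 14, 7 fell and 7 were not called, 9 passed adjusted over the list alone) fell with Cplx1 (-0.62 ± 0.10) and Nefm (-0.62 ± 0.12). By camera, thalamic markers had adjusted p = 0.0167, and adjusted p = 0.0377 with an estimated correlation. Markers of amygdala and piriform cortex (of 11, 6 fell and 5 were not called, 7 passed adjusted over the list alone) fell with Lypd1 (-0.83 ± 0.11), Grp (-0.75 ± 0.12) and Cartpt (-0.96 ± 0.19). For amygdala and piriform markers camera gave adjusted p = 0.0155, and adjusted p = 0.106 with an estimated correlation. Immediate early genes, which report recent neuronal activity (of 21, 9 fell and 12 were not called, 10 passed adjusted over the list alone), were lower with Egr1 (-0.49 ± 0.10) and Trib1 (-0.57 ± 0.17). Immediate early genes had a camera adjusted p of 0.032, and adjusted p = 0.161 with an estimated correlation. Markers of immature neurons (of 15, 8 fell, 1 rose and 6 were not called, 10 passed adjusted over the list alone), with Dpysl3 at -0.70 ± 0.13, lost their call after quantile normalization (0.0989). By camera, immature neuron markers had adjusted p = 0.0252, and adjusted p = 0.382 with an estimated correlation. Oxidative phosphorylation (of 41, 13 rose, 4 fell and 24 were not called, 19 passed adjusted over the list alone) was shifted up, with Atp5me (0.86 ± 0.11) and Atp5f1b (0.69 ± 0.12). For oxidative phosphorylation genes camera gave adjusted p = 0.0155, and adjusted p = 0.682 with an estimated correlation. Haemoglobin genes Hbb-b1 (0.68 ± 0.12) and Hbb (0.67 ± 0.13) rose in the red blood cell list (of 10, 3 rose and 7 were not called, 3 passed adjusted over the list alone), and olfactory and vomeronasal receptors were higher (of 1232, 190 rose, 20 fell and 1022 were not called, 188 passed adjusted over the list alone). In turn for red blood cell genes and olfactory and vomeronasal receptors, camera gave adjusted p = 0.0183 and adjusted p = 1.65e-05. Estimating the correlation gave adjusted p = 0.134 and adjusted p = 0.00642. By limma 2497 rose and 4226 fell among the features, and the count grew to 11039 with array weights and to 10148 in a fit of these 2 groups alone.

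Adult exposed rats had lower immediate early, interneuron and red blood cell genes in the amygdala. Their arrays were split on the second principal component, replicates 1 and 2 at 2.69 and 6.10 and replicates 3 to 5 at -19.3 to -16.7, and 5387 and 4481 features were called for each set alone. On the first component they stood at 67.1, 65.5, 11.2, 38.4 and -0.298 by replicate, against -12.8 to 8.37 in controls. Egr2 fell by 1.64 ± 0.13, Grp by 1.56 ± 0.12, Pdyn by 1.55 ± 0.16 and Cartpt by 1.42 ± 0.19. Of 21 immediate early genes 12 fell and 9 were not called (12 passed adjusted over the list alone), including Egr1 (-0.93 ± 0.10), Nr4a1 (-0.82 ± 0.15) and Egr3 (-0.64 ± 0.12). For immediate early genes camera gave adjusted p = 2.74e-06, and adjusted p = 0.00268 with an estimated correlation. Markers of amygdala and piriform cortex (of 11, 8 fell, 1 rose and 2 were not called, 9 passed adjusted over the list alone), with the zinc transporter gene Slc30a3 (-1.02 ± 0.13), fell beside them. Amygdala and piriform markers had a camera adjusted p of 1.51e-05, and adjusted p = 0.00601 with an estimated correlation. Ptprs (1.84 ± 0.14), Vmp1 (1.51 ± 0.12) and Ccn2 (1.39 ± 0.17) rose.

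Interneuron peptides were lower, Cck at -1.22 ± 0.090, Npy at -1.24 ± 0.11 and Sst at -0.97 ± 0.098, in a list where, of 20, 9 fell, 2 rose and 9 were not called (11 passed adjusted over the list alone). By camera, interneuron genes had adjusted p = 0.00186, and adjusted p = 0.0311 with an estimated correlation. Striatal projection neuron markers (of 19, 7 fell, 1 rose and 11 were not called, 8 passed adjusted over the list alone) fell with Drd2 (-1.23 ± 0.13) and Ppp1r1b (-1.16 ± 0.14), and thalamic markers (of 14, 6 fell, 1 rose and 7 were not called, 8 passed adjusted over the list alone) with Six3 (-1.18 ± 0.12) and Lef1 (-1.21 ± 0.16). For striatal markers and thalamic markers, camera gave adjusted p = 0.00259 and adjusted p = 0.00574. At an estimated correlation they had adjusted p = 0.151 and adjusted p = 0.0207. The adult haemoglobin genes Hba-a2 (-1.21 ± 0.12), Hba-a1 (-1.16 ± 0.13) and Hbb-b1 (-1.25 ± 0.12) fell in the red blood cell list (of 10, 4 fell and 6 were not called, 4 passed adjusted over the list alone). By camera, red blood cell genes had adjusted p = 0.00186, and adjusted p = 0.0311 with an estimated correlation. Astrocyte genes (of 20, 10 rose, 2 fell and 8 were not called, 14 passed adjusted over the list alone) rose with Slc6a11 (0.84 ± 0.12), Slc1a3 (0.75 ± 0.11) and Gfap (0.76 ± 0.14), and cholesterol synthesis (of 22, 9 rose, 1 fell and 12 were not called, 10 passed adjusted over the list alone) with Hmgcs1 (0.85 ± 0.11), although the cholesterol score did not separate the arms in exact permutations (adjusted p = 0.0714). In turn for astrocyte markers and cholesterol synthesis, camera gave adjusted p = 0.00186 and adjusted p = 0.00574. The estimated correlation gave adjusted p = 0.151 and adjusted p = 0.151. Limma called 5577 features, of which 2471 rose and 3106 fell, and camera called 8 of 33 lists. A fit of these 2 groups alone called 3284.

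**Figure D2:**
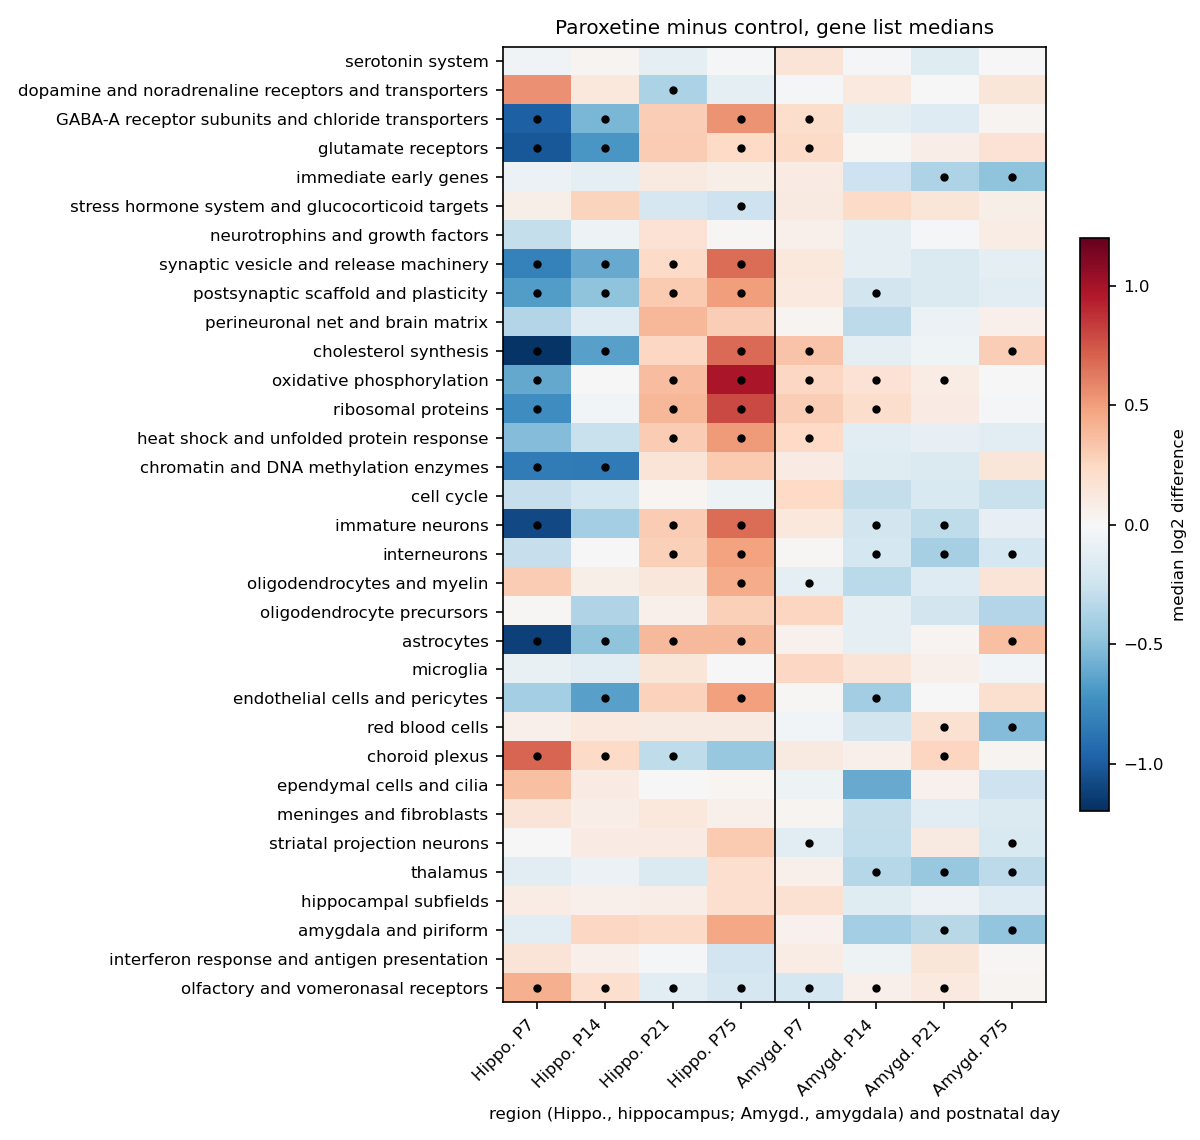
Median log2 difference, paroxetine minus control, of the measured members of 33 gene lists (rows) in the 8 comparisons of region and postnatal day (columns). Colour gives the median and black dots mark camera adjusted p under 0.05; cholesterol synthesis is at -1.18 in the hippocampus at P7 and at 0.68 at P75.

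Genes of the serotonin system, the direct target of paroxetine, changed singly and not as a group, since the list of 20 measured genes was called in none of the 8 comparisons (hippocampus at P7, 7 rose, 3 fell and 10 were not called, 10 passed adjusted over the list alone, camera adjusted p = 0.305). Htr2c, the 5-HT2C receptor gene, fell in the hippocampus at P7 (-1.37 ± 0.26) and P14 (-1.89 ± 0.25), was not called at P21 (-0.20 ± 0.25) and rose at P75 (2.19 ± 0.25). Its control level went from 8.33 at P7 and 8.73 at P14 to 6.06 at both P21 and P75, whereas exposed arrays stood at 6.96, 6.85, 5.86 and 8.25. The levels of both arms at P21 and of controls at P75 lay at the floor, since olfactory and vomeronasal receptors averaged 6.26 to 6.43 on those arrays, and exposed levels at P7 and P14 were little above these receptors (6.38 to 6.46 and 6.28 to 6.31), so that the P21 difference and the sizes of the others cannot be read as given. In the amygdala Htr2c was not called at any age (0.31 ± 0.27, 0.27 ± 0.25, -0.10 ± 0.25 and 0.53 ± 0.25 in order of age). Htr1a, the 5-HT1A autoreceptor and postsynaptic receptor gene, fell in the hippocampus at P7 (-0.75 ± 0.14) and P14 (-0.83 ± 0.14) and was not called at P21 or P75 (0.01 ± 0.14 and -0.08 ± 0.14). The transporter gene Slc6a4 rose in the hippocampus at P7 (0.88 ± 0.21) and was called nowhere else, but its levels there (6.33 in controls and 7.22 in exposed pups) were little above the receptors of the nose (5.93 to 5.98 and 6.38 to 6.46 by array), which rose as well. Htr1b fell in the amygdala at P75 (-0.65 ± 0.16) and at P14 (-0.47 ± 0.16), the latter not without control replicate 1 (adjusted p = 0.0558). Htr2a rose in the amygdala at P7 (0.71 ± 0.16). Its hippocampal rise at P75 (0.49 ± 0.17) lost the call without control replicate 3 (0.0551) or 5 (0.0661) or exposed replicate 5 (0.0569).

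**Figure D3:**
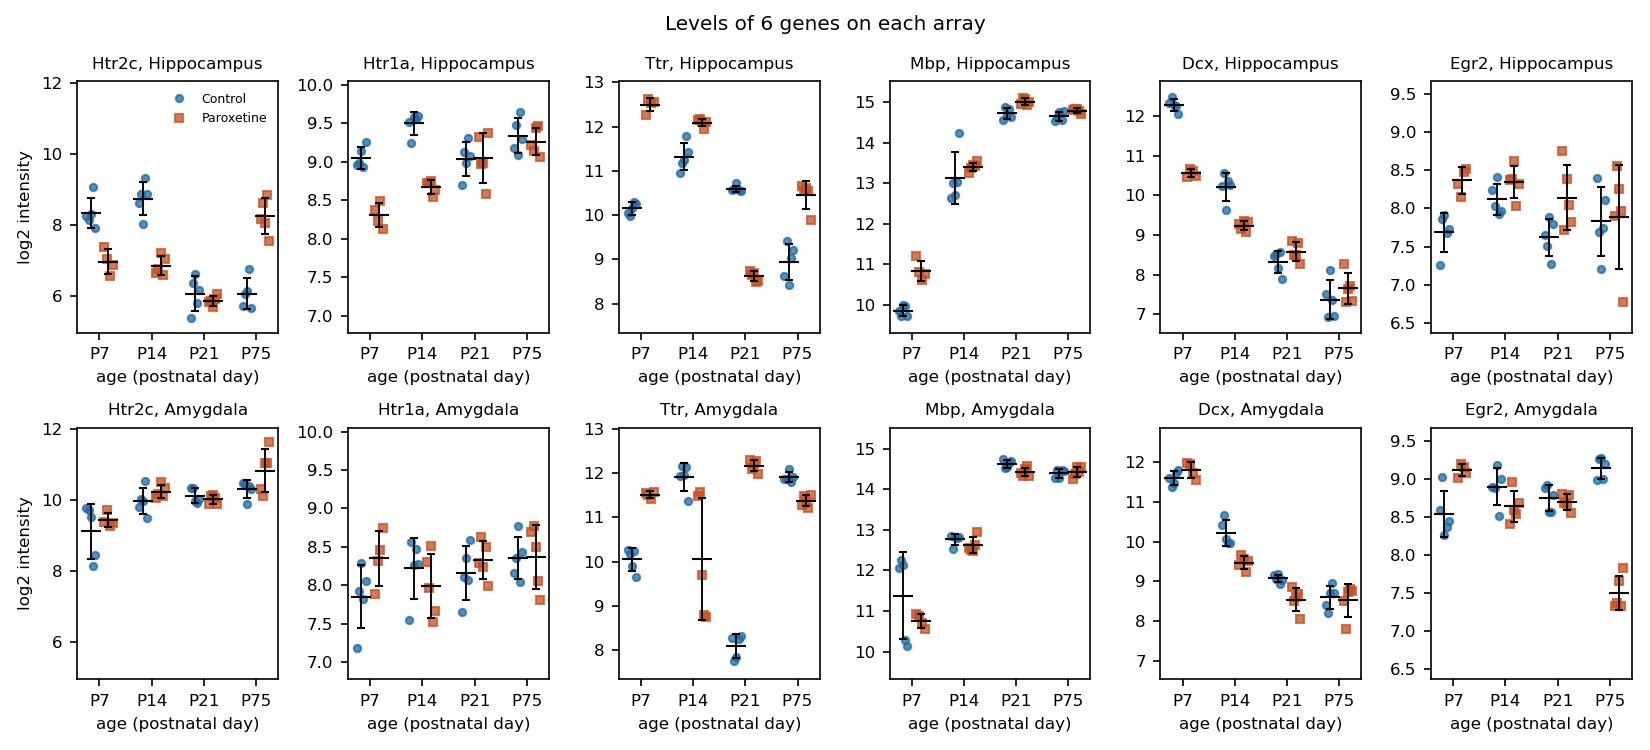
Log2 intensity of Htr2c, Htr1a, Ttr, Mbp, Dcx and Egr2 on each array, by age in postnatal days, in hippocampus (top) and amygdala (bottom). Points are arrays, circles controls and squares paroxetine, and black bars give mean ± SD; hippocampal Htr2c averages 6.06, at the floor, in controls and 8.25 in exposed rats at P75.

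Averaged over the 4 ages, the exposed hippocampus had lower Tbc1d14 (-1.42 ± 0.098), Vmp1 (-1.17 ± 0.081) and Ptprs (-1.11 ± 0.062) and higher 4930488N24Rikl (1.25 ± 0.11) and Spdye4 (1.12 ± 0.17). Glutamate receptors (of 19, 12 fell and 7 were not called, 12 passed adjusted over the list alone), cholesterol synthesis (of 22, 15 fell, 1 rose and 6 were not called, 18 passed adjusted over the list alone) and astrocyte markers (of 20, 11 fell, 3 rose and 6 were not called, 14 passed adjusted over the list alone) were lower on average, with Grm5 (-0.75 ± 0.085), Insig1 (-0.74 ± 0.075) and Gja1 (-0.58 ± 0.048). For glutamate receptors, cholesterol synthesis and astrocyte markers, camera gave adjusted p = 0.0012, adjusted p = 0.000213 and adjusted p = 0.00761. They had adjusted p = 0.0479, adjusted p = 0.0486 and adjusted p = 0.0479 with an estimated correlation. These lists and Ptprs were lower at P7 and P14 but higher at P75. Ribosomal protein genes (of 65, 23 rose, 9 fell and 33 were not called, 32 passed adjusted over the list alone) were higher, with Rpl41 at 0.62 ± 0.047. By camera, ribosomal proteins had adjusted p = 5.31e-05, and adjusted p = 0.0479 with an estimated correlation. Oxidative phosphorylation (of 41, 18 rose, 9 fell and 14 were not called, 29 passed adjusted over the list alone), myelin (of 22, 12 rose, 4 fell and 6 were not called, 16 passed adjusted over the list alone), amygdala and piriform (of 11, 5 rose, 2 fell and 4 were not called, 8 passed adjusted over the list alone) and olfactory and vomeronasal receptor genes (of 1232, 186 rose, 33 fell and 1013 were not called, 156 passed adjusted over the list alone) were shifted up too. In turn for oxidative phosphorylation genes, myelin genes, amygdala and piriform markers and olfactory and vomeronasal receptors, camera gave adjusted p = 0.00101, adjusted p = 0.0436, adjusted p = 0.0193 and adjusted p = 3.16e-05. These had adjusted p = 0.0561, adjusted p = 0.255, adjusted p = 0.0479 and adjusted p = 1.11e-05 with an estimated correlation. Quantile normalization ended the myelin call (0.114). On average the amygdala had lower Spdye4 (-1.53 ± 0.17), Mospd3 (-1.24 ± 0.054), Cartpt (-1.04 ± 0.095) and Phlda1 (-1.01 ± 0.048) and higher Fdcsp (1.39 ± 0.20) and Mall (1.21 ± 0.14). Interneuron genes (of 20, 10 fell, 2 rose and 8 were not called, 12 passed adjusted over the list alone) and immediate early genes (of 21, 10 fell and 11 were not called, 10 passed adjusted over the list alone) were lower, with Cck (-0.85 ± 0.046) and Egr1 (-0.55 ± 0.051). For interneuron genes and immediate early genes, camera gave adjusted p = 0.00528 and adjusted p = 0.0113. Estimating the correlation gave adjusted p = 0.0783 and adjusted p = 0.0903. Markers of amygdala and piriform cortex (of 11, 6 fell, 2 rose and 3 were not called, 8 passed adjusted over the list alone) and of thalamus (of 14, 7 fell, 3 rose and 4 were not called, 11 passed adjusted over the list alone) were lower as well. In turn for amygdala and piriform markers and thalamic markers, camera gave adjusted p = 0.00916 and adjusted p = 0.0145. At an estimated correlation they had adjusted p = 0.0903 and adjusted p = 0.0783. Oxidative phosphorylation genes were higher (of 41, 21 rose, 8 fell and 12 were not called, 29 passed adjusted over the list alone). By camera, oxidative phosphorylation genes had adjusted p = 0.00528, and adjusted p = 0.555 with an estimated correlation. Limma called 9128 features in the hippocampus, of which 4055 rose and 5073 fell, and 10939 in the amygdala, of which 5336 rose and 5603 fell.

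Differences between exposed and control arrays varied with age for single genes in both regions. In the hippocampus the 4 differences of Ptprs spanned 5.58 log2 units, those of Cpg1 6.55 and those of the neuronal enolase gene Eno2 4.17, and limma called 16789 features for an age-by-treatment interaction. In the amygdala Ttr spanned 5.94, Fads2 1.70 and Egr2 2.21, and 8631 features were called. Differences also varied between the regions at a given age, as did those of the random control probe, for example 8.99 intensity units in the hippocampus and -4.27 in the amygdala at P7. At P7 the synaptic scaffold gene Dlg2 (-2.90 ± 0.14), Ptprs (-3.84 ± 0.19) and Snurf (-2.56 ± 0.13) had lower differences in the hippocampus than in the amygdala (values are the hippocampal minus the amygdalar difference), and Cck (1.45 ± 0.13) the other way. At P21 Ttr differed by -6.06 ± 0.36. At P75 the autophagy gene Map1lc3a (2.21 ± 0.14) and the ribosomal gene Rpl41 (1.85 ± 0.13) rose in the hippocampus and fell in the amygdala, and Cpg1 (-3.28 ± 0.39) fell in the hippocampus and was not called in the amygdala (0.16 ± 0.35). The region-by-treatment term was called for 13055, 7428, 9938 and 9757 features at the 4 ages in order. The region values appeared to have been normalized separately.

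Between P7 and P75 the control brain laid down myelin and lost markers of immature neurons. In the control hippocampus Mobp (5.32 ± 0.20) and Mbp (4.80 ± 0.17) rose, and of 22 myelin genes 19 rose, 2 fell and 1 was not called (21 passed adjusted over the list alone). For myelin genes camera gave adjusted p = 2.13e-11, and adjusted p = 0.000429 with an estimated correlation. Doublecortin, encoded by Dcx (-4.91 ± 0.19), fell with Dpysl3 (-5.23 ± 0.12) and Tubb2b (-4.62 ± 0.092), as did 14 of 15 such markers (14 passed adjusted over the list alone). Immature neuron markers had a camera adjusted p of 1.6e-14, and adjusted p = 2.65e-05 with an estimated correlation. Cholesterol synthesis (of 22, 20 fell and 2 were not called, 20 passed adjusted over the list alone) and ribosomal proteins (of 65, 61 fell, 2 rose and 2 were not called, 63 passed adjusted over the list alone) declined, with Sqle (-2.62 ± 0.14) and Rpsa (-2.54 ± 0.095). For cholesterol synthesis and ribosomal proteins, camera gave adjusted p = 1.52e-09 and adjusted p = 4.59e-20. The estimated correlation gave adjusted p = 0.00159 and adjusted p = 2.65e-05. The control amygdala moved alike for Mobp (3.36 ± 0.40) and Mbp (3.02 ± 0.25) and Dpysl3 (-4.07 ± 0.13) and Dcx (-3.00 ± 0.17). There myelin genes (of 22, 20 rose and 2 were not called, 21 passed adjusted over the list alone) rose, immature neuron markers (of 15, 13 fell and 2 were not called, 14 passed adjusted over the list alone) and cholesterol synthesis (of 22, 17 fell, 1 rose and 4 were not called, 18 passed adjusted over the list alone) fell, and microglial genes (of 20, 12 rose and 8 were not called, 13 passed adjusted over the list alone) rose with Ctss (1.66 ± 0.21) and Csf1r (0.71 ± 0.14). In turn for myelin genes, immature neuron markers, cholesterol synthesis and microglial genes, camera gave adjusted p = 1.48e-17, adjusted p = 5.67e-26, adjusted p = 1.71e-14 and adjusted p = 0.00306. They had adjusted p = 0.00769, adjusted p = 3.24e-06, adjusted p = 9.58e-05 and adjusted p = 0.0197 with an estimated correlation. Limma called 15799 features in the hippocampus, of which 7761 rose and 8038 fell, and 6723 in the amygdala, of which 3652 rose and 3071 fell. With the random probe as covariate 541 were called in the hippocampus. After quantile normalization 49.4% of the amygdalar calls were rises, against 54.3% before. By step, the hippocampal controls changed 5715 features from P7 to P14, 14258 from P14 to P21 and 670 from P21 to P75, and the amygdalar controls 1889, 3265 and 1018. In hippocampal controls the random control probe stepped up between P14 and P21 too (43.97, 45.2, 55.19 and 56.29 at the 4 ages), and the interquartile range stepped down (3.21, 3.14, 2.74 and 2.72), so age was not separable by label from an array batch in these counts either.

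In a comparison added after the data had been examined, the exposed hippocampus also gained myelin transcripts and lost immature neuron markers from P7 to P75. Mobp and Mbp changed by 4.41 ± 0.21 and 3.95 ± 0.18 in the exposed hippocampus, and Dcx and Dpysl3 by -2.90 ± 0.20 and -3.16 ± 0.13. All 22 myelin genes rose (22 passed adjusted over the list alone) and all 15 immature neuron markers fell (15 passed adjusted over the list alone). For myelin genes and immature neuron markers, camera gave adjusted p = 1.66e-21 and adjusted p = 2.05e-18. These had adjusted p = 3.2e-06 and adjusted p = 3.2e-06 with an estimated correlation. Of 2853 genes called in both arms (2329.66 for independent lists), 726 changed the same way and 2127 the opposite way, and the 2 arms' changes correlated at r = -0.228 across genes, which are not independent replicates. The random control probe also moved in opposite directions from P7 to P75, from 43.97 to 56.29 in controls and from 52.97 to 49.0 in exposed arrays, and so did the interquartile range (3.21 to 2.72 and 2.79 to 2.97). Ptprs, for example, changed by -4.36 ± 0.12 in controls and by 1.22 ± 0.13 in exposed rats, and Cpg1 by 4.43 ± 0.17 and -2.12 ± 0.18. In the amygdala 1442 of 1565 genes called in both arms (963.26 for independent lists) changed the same way and 123 the opposite way (r = 0.527).

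**Figure D4:**
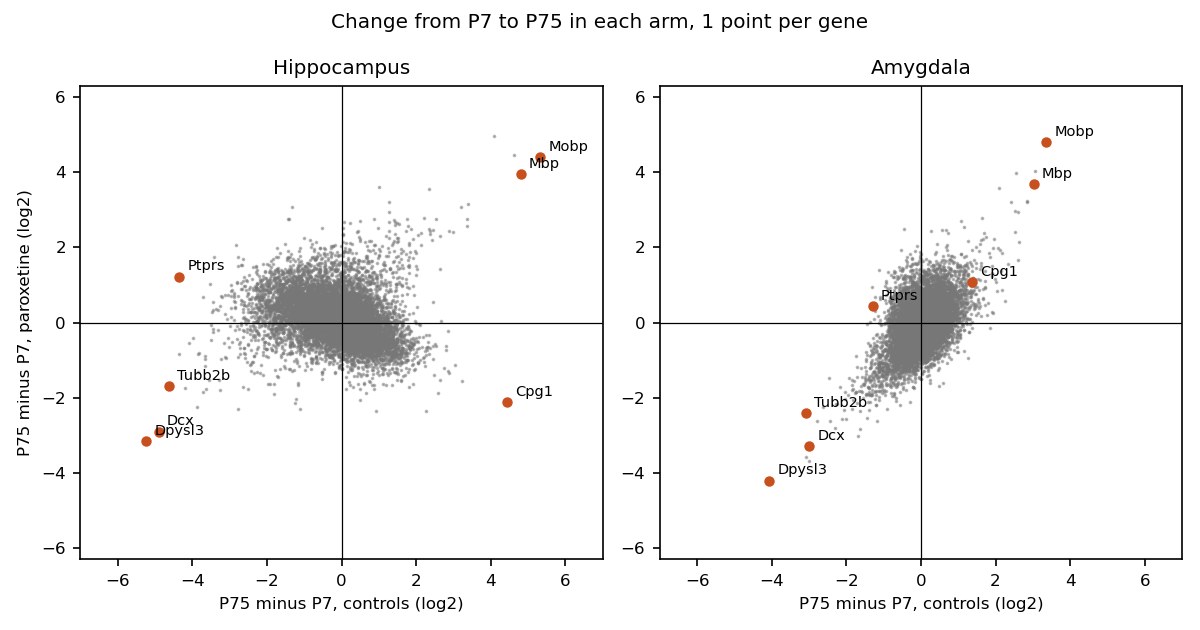
Change from P7 to P75 in log2 units in control (horizontal) against exposed rats (vertical) for hippocampus (left) and amygdala (right), with 1 point per gene. Orange points name genes given in the report; the labelled myelin genes lie at the upper right and the labelled markers of immature neurons at the lower left in both regions, while Ptprs and Cpg1 lie in opposite quadrants in the hippocampus.

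Control hippocampus and amygdala were compared as a check of the region labels. Lypd1 (-3.28 ± 0.066), the enkephalin gene Penk (-3.59 ± 0.062), Calb2 (-3.00 ± 0.075) and Atp2b4 (-3.78 ± 0.060) were lower in the hippocampus, where values are hippocampus minus amygdala averaged over ages. Markers of amygdala and piriform cortex (of 11, 10 were lower and 1 was higher, 11 passed adjusted over the list alone), striatal markers (of 19, 16 were lower and 3 were not called, 16 passed adjusted over the list alone) and interneuron genes (of 20, 17 were lower, 2 were higher and 1 was not called, 19 passed adjusted over the list alone) followed. In turn for amygdala and piriform markers, striatal markers and interneuron genes, camera gave adjusted p = 2.68e-05, adjusted p = 1.25e-05 and adjusted p = 6.76e-05. Estimating the correlation gave adjusted p = 0.000299, adjusted p = 0.00134 and adjusted p = 0.0137. Stress hormone genes were higher in the hippocampus (of 22, 13 were higher, 6 were lower and 3 were not called, 20 passed adjusted over the list alone), among them the mineralocorticoid receptor gene Nr3c2 (1.48 ± 0.069). Stress hormone genes had a camera adjusted p of 0.00371, and adjusted p = 0.0707 with an estimated correlation. Limma called 17076 features, of which 6613 were higher and 10463 lower in the hippocampus.

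The authors' deposited tables list features with a Bonferroni corrected p of at most 0.05 and a fold change of at least 1.5 in each region and age. In the authors' deposited tables for the hippocampus 31 features were higher and 691 lower at P7, 5 and 302 at P14, 44 and 36 at P21, and 316 and 44 at P75. For the amygdala the authors' deposited tables hold 3 higher and 0 lower features at P7, 34 and 116 at P14, 70 and 117 at P21, and 26 and 54 at P75. Ttr leads the amygdala P21 table with a fold of 16.96. All listed features had the same direction in the value table, with folds within 0.01 log2 units, and limma called all of them except 1 of 80 in the hippocampus at P21.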

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

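The tests of quantile normalization at P7, of genes rising with age, of choroid plexus markers and of the region difference for transthyretin, and of the amygdala and piriform list were chosen only after the result was seen. Single arrays stood apart from the rest of their group by the gap to the nearest array over the group's range, a measure that chance alone lifts above its limit in about 1 in 20 groups. Of 32 tests on array measures 1 did so, the interquartile range of amygdala P14 control replicate 5 (0.718), and of 336 tests on genes 15 did. In the hippocampus these were 4930488N24Rikl in P7 control replicate 5 (0.861), Cpg1 in P14 control replicate 5 (0.734), Ptprs in P14 exposed replicate 5 (0.727), Htr1a in P14 control replicate 2 (0.776), H2ac1 in P21 exposed replicate 1 (0.791), C6h14orf180 in P21 control replicate 4 (0.764), Ttr in P21 control replicate 3 (0.733), Atp2b4 in P75 control replicate 5 (0.861) and Itm2c in P75 control replicate 2 (0.774). In the amygdala they were Fdcsp in P14 control replicate 4 (0.727), RT1-CE11 in P14 exposed replicate 5 (0.794), Pcbd1 in P21 exposed replicate 1 (0.778), Gabrg3 in P21 control replicate 4 (0.772), Phlda1 in P75 control replicate 1 (0.741) and Htr2c in P75 control replicate 3 (0.719).

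Differences between exposed and control rats varied between ages or regions by limma interaction terms, for 16789 features over the ages in the hippocampus and 8631 in the amygdala, and for 13055, 7428, 9938 and 9757 between regions at P7, P14, P21 and P75. Over the 4 ages the hippocampal differences spanned 5.58 log2 units for Ptprs, 4.17 for Eno2, 6.55 for Cpg1, 3.66 for Prkar1a and 4.00 for Nsg1, and the amygdalar ones 5.94 for Ttr, 1.70 for Fads2, 1.93 for Hbb-b1, 2.21 for Egr2 and 1.94 for Tppp3. The hippocampal minus the amygdalar difference at P7 was 1.45 for Cck, 3.31 for Pde6h, 1.21 for Prr13, -2.90 for Dlg2, -3.84 for Ptprs and -2.56 for Snurf. At P14 it was 1.66 for Cck, 2.11 for Mospd3, 1.31 for Pfn1, -3.30 for Ptprs, -3.55 for Vmp1 and -2.46 for Mmd2. At P21 the values were 1.41 for Cend1, 1.36 for Cck, 1.79 for Mospd3, -6.06 for Ttr, -3.60 for Slc22a18 and -1.99 for Aldh2. At P75 they were 2.21 for Map1lc3a, 1.85 for Rpl41, 1.70 for Nedd8, -1.90 for C5h1orf174, -3.28 for Cpg1 and -1.18 for Kpna2. The random control probe, which enters no comparison of genes, was above the control arrays by 8.99 and 3.37 intensity units on exposed hippocampal arrays at P7 and P14 and by 1.40 on exposed amygdalar arrays at P21.

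In the hippocampus at P7, 14096 of 26419 features were called. Array spread left by the authors' normalization was argued against as the whole cause, since 82.97% of these calls were made again in the same direction after quantile normalization. An unlabelled array batch stays open, beside an effect of paroxetine itself, and had the value it needs, because 37.34% of receptor genes near the floor were called, against 53.6% of all genes. Earlier maturation of exposed pups could be neither excluded nor shown, with r = 0.2969 across genes against the P75 minus P7 change of amygdala controls. Genes that fell with age there had a median P7 difference of -0.8783, as maturation would have it, the median of 0.05713 of genes that rose decides nothing, since 672 were higher and 598 lower, and astrocyte markers went against it (medians of 0.27 with age and -1.12 at P7).

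At P21 exposed pups had higher amygdalar and lower hippocampal Ttr. The region difference of -6.06 restates this and decides nothing about a batch. Choroid plexus tissue carried along in some dissections could contribute, but the other 14 choroid plexus markers had a median of 0.2307 in the amygdala and -0.2909 in the hippocampus, and only for the amygdala had bounds been set, between which it lies. A paroxetine effect stays open and was not tested apart from a batch, and the random probe moved by 1.40 units in the amygdala and -7.547 in the hippocampus.

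Immediate early genes were lower in the amygdala of exposed rats at P75. In exposed arrays 1 and 2 and in arrays 3 to 5, subsets taken from a principal component after the data were seen, the list medians were -0.552 and -0.44. That bound was wrongly written as evidence against a batch, since both subsets share their controls, so a batch between the arms stays open. Less amygdala in the dissection may contribute, with a median of -0.4718 for the amygdala and piriform list. The striatal and thalamic lists, of neighbouring regions, fell too, so this decides nothing. A lasting paroxetine effect stays open and was not tested apart from a batch or dissection.

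In each of 19 results the real array grouping was the only 1 of 100 splits with a count as large. In the hippocampus the real counts at P7, P14, P21 and P75 were 14096, 10101, 6977 and 11198, and the highest of the other splits 11382, 4277, 31 and 3902. In the amygdala they were 2069, 9460, 6723 and 5577 against 959, 2647, 2 and 2110. The average effects (9128 and 10939) stood against 2 and 7, and the age by treatment terms (16789 and 8631) against 6677 and 2963, for hippocampus and amygdala in turn. The region by treatment terms (13055, 7428, 9938 and 9757) stood against 8662, 5075, 2153 and 5225. P75 against P7 in controls (15799 and 6723) stood against 9117 and 2476, and the regions in controls (17076) against 11223. A batch or litters that follow the groups would pass too, and splits do not isolate an interaction.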

How the results depend on the processing

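Fits on array subsets and with the random probe as a covariate were chosen after seeing the data. Trend and robust moderation, or fitting all 78 arrays, kept every count within 1.5 times. The majority direction turned in 2 comparisons. In the amygdala at P7 the higher share of calls went from 72.3% to 47.9% after quantile normalization and 39.4% with the random probe as covariate, and for its P75 against P7 in controls from 54.3% to 49.4% after quantile normalization. Among features called in both fits at most 16 had opposite signs, for the regions after quantile normalization. The amygdala at P7 (2069 calls) had 1087 after quantile normalization, 5 in a fit of the 2 groups alone, 175 by t-test with Benjamini-Hochberg adjustment, 5018 by t-test at unadjusted 0.05, and 267 with exposed arrays 1 and 2 only, for which the cause was not tested. Array weights gave 11039 in the amygdala at P21, and 2-group fits 10148 there and 3284 at P75, where the adjusted t-test gave 3208. Unadjusted t-tests gave 10685 in the hippocampus and 12034 in the amygdala at P21. With control arrays 1 to 3 only, the hippocampus at P14 had 6147. Without the dimmer features fewer were tested (13209), leaving 10861 for the hippocampal age by treatment term, 10026 for hippocampal P75 against P7 and 10790 for the regions. The random probe as covariate left 1712, 4624, 2 and 114 calls in the hippocampus at P7, P14, P21 and P75, 541 for its P75 against P7 in controls, and 269 in the amygdala at P7, where it follows the groups and raised the median standard error 1.45 to 4.56 times. The covariate left 10034, 5024 and 4454 in the amygdala at P14, P21 and P75, 8729 and 9113 for the averages and 5954 for amygdalar P75 against P7, all within 1.5 times, with standard errors 1.03 to 1.55 times as large. List shifts over the 8 comparisons numbered 82 with the preset correlation, 34 with an estimated correlation and 141 by exact permutation.

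Leaving out 1 array gave 13223 to 13638, 8432 to 10224, 5576 to 6360 and 10441 to 10827 calls in the hippocampus by age and 961 to 2049, 8550 to 9289, 5664 to 6088 and 4759 to 5624 in the amygdala. The ranges were 8607 to 9345 and 10458 to 11264 for the average effects, 16434 to 16852 and 7456 to 9122 for age by treatment, 12420 to 12868, 6980 to 7451, 9309 to 9689 and 8671 to 10392 for region by treatment, 14995 to 15362 and 5851 to 6674 for P75 against P7, 16809 to 17147 for the regions, and 79 to 84 for list shifts.

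The replicate numbers were not taken to pair the arrays, since 0 of 38 pairs of control and exposed arrays and 0 of 39 pairs of regions deviated together at r above 0.1, although 8 and 14 correlated best with their own number, the latter with 5 of 5 controls at P75 and 4 of 5 at P21. With the number as a replicate block the counts were 13279, 9712, 6295 and 10782 in the hippocampus, 783, 9056, 6236 and 5025 in the amygdala, 8530 and 10425 for the averages, 16084 and 6451 for age by treatment, 12952, 7326, 9836 and 9618 for region by treatment, 15593 and 6309 for P75 against P7, 17024 for the regions and 81 for list shifts. Among list calls the block ended 5, in the amygdala GABA-A receptors at P7 (0.0598), interneurons and thalamus at P14 (0.062 and 0.0529) and oxidative phosphorylation over age in controls (0.051), and stress hormones over age in hippocampal controls (0.0503). No depth is known for arrays, and features near the floor have little signal over background.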

Other observations

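Across genes, which are not independent replicates, amygdalar differences correlated at r = 0.735 between P14 and P21, r = 0.536 between P14 and P75 and r = 0.607 between P21 and P75, but at r = -0.0672, r = -0.127 and r = -0.023 between P7 and these ages. In the hippocampus P21 and P75 correlated at r = 0.638, whereas P21 against P7 and P14 gave r = -0.418 and r = -0.271, and P75 against P14 r = -0.581.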
